A study of Homo sapiens with 5 samples.

How the data were processed

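Per the labels' protocols, total RNA of 3 wild type and 2 METAP1 knockout samples of HAP1 cells was depleted of ribosomal RNA, made into stranded libraries and sequenced with single-end reads on an Illumina instrument. The submitters' processing notes list STAR 2.4.0i, HTSeq and DESeq2 and the human builds GRCh37 and hg19, without saying what each did, and the strand setting of the counting is not given in the sources used here. One deposited table of 10626 genes was used. It held, per the file headers, raw read counts and RPKM values for each library, which the authors deposited beside a comparison of their own: a mean signal over libraries, log2 fold changes with standard errors, a test score, and p-values with adjusted p-values. The authors' mean signal was recomputed from the counts with median-of-ratios size factors of the table's own genes, with a largest relative gap of 5.33e-15. The authors' RPKM values divide the counts by a library total larger than the table's sum, and the table held 89.1, 91.2 and 91.0% of that total in wild type replicates 1 to 3. The smallest RPKM in these 3 libraries was 1.001. From the counts, the smallest value in the knockout libraries was 1.11 when the table's own totals were used instead.

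The read columns were matched to the sample labels by name. Wild type columns carried the numbers of the sample titles. The knockout columns were numbered 2 and 3 and the titles number the samples otherwise, so both were used as knockout libraries without tying each to a title. The 2 RPKM columns of the knockout were not used. Depth per library is the sum of the table's reads, given in the report. Gene identity came from the Ensembl identifiers: 10514 matched the reference names, and 18 gene names that had been turned into dates were resolved by identifier. Positions came from GENCODE release 29 (GRCh38) by identifier for 10521 genes, and none was converted between builds.

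Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr (which removed 6 genes), TMM normalization, robust dispersion estimates, and a 2-sided quasi-likelihood F-test of knockout against wild type over the 5 libraries with no covariate. Adjusted p-values are Benjamini-Hochberg values over the 10620 tested genes, and a gene was called at an adjusted p under 0.05. A normalized count is a count divided by the library's effective size relative to the mean effective size, and standard errors were derived from the fold change and the F statistic. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 26 lists with at least 3 measured members. Camera was run again with an estimated correlation, and 3 of the 13 called lists held. The residual degrees of freedom were 3 and the common biological coefficient of variation was 11.7%.

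Genes were named by a rule. METAP1, METAP2 and METAP1D came first. Next came the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, with at least 100 normalized counts in the higher group and no clone-type name. From each gene list up to 4 called members with the smallest adjusted p were taken (or the most abundant members as values), and then the 5 most abundant called genes. Some genes that the rule selects are not reported here. The rule, the 27 lists and the following other settings were written before the data were examined: median-of-ratios size factors, no filter, a mean of at least 50 counts, each library left out in turn, DESeq2 1.42.0, limma-voom, camera with an estimated correlation and fry. Library sizes without TMM, removal of each library's trend with gene length or with GC content (lowess, span 0.3), and a block by column numbers were added after seeing the data.

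The steps were tested on simulated counts drawn for the same 10620 genes and library sizes, with 200 genes changed. For knockout against wild type, 26.9% of genes changed by a log2 fold change of 0.5 were recovered, 94.0% at 1 and 100% at 2. Of called genes, 9.04% were unchanged ones, which is above the share that the adjusted p threshold aims for. The data had 3150 called genes against 200 changed ones here, so these rates may not carry over. A planted list was called and 0 of 25 unchanged lists were. Shared variation of list members was not part of this check. It therefore cannot decide how the preset correlation fares for lists such as ribosomal proteins, with an estimated correlation of 0.731. Replicates were compared before averaging: chi-square per degree of freedom lay between 10.1 and 34.9 within groups, so no pair of libraries agreed within sampling noise. Genes along chromosomes were scanned in windows of 30 neighbouring genes against 1000 permutations of gene order, with 95% bootstrap intervals from 2000 draws over genes. These used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.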

Results

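RNA sequencing compared parental HAP1 cells with a METAP1 knockout line. HAP1 is a near-haploid human cell line that came from a chronic myeloid leukaemia line, and METAP1 encodes methionine aminopeptidase 1, an enzyme that removes the first methionine from newly made proteins. The comparison asked how transcript levels differ when METAP1 is disrupted. There were 3 wild type libraries and 2 knockout libraries. The table held 13111303, 16519292 and 14722649 reads for wild type replicates 1, 2 and 3, and 12570051 and 13061232 for the knockout libraries, numbered 2 and 3 in the table. It covered 10626 genes, all with an RPKM of at least 1 in the wild type libraries and at least 1.11 in the knockout libraries when computed from the counts and the table's own totals. A gene near zero in either group was therefore not analysed here. The labels call the libraries biological replicates without saying how the cultures were kept apart, and they describe 1 edited line. The p-values below therefore measure the spread between these libraries, and genotype could not be separated from clone.

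METAP1 transcripts were lower in both knockout libraries, whereas transcripts of the related enzymes METAP2 and METAP1D showed no detectable difference. METAP1 (ENSG00000164024) had 1914 ± 40.5 normalized counts in wild type cells (SD, n = 3) and 679 ± 96.9 in the knockout (SD, n = 2). Its log2 fold change was -1.49 with a standard error of 0.115 (adjusted p = 9.33e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The knockout thus kept METAP1 RNA at 0.355 times the wild type level. METAP2, the other cytosolic methionine aminopeptidase, had 2911 ± 117 (SD, n = 3) and 2676 ± 292 normalized counts (SD, n = 2), and METAP1D, the mitochondrial form, had 282 ± 10.9 (SD, n = 3) and 292 ± 26.5 (SD, n = 2). Their log2 fold changes were -0.12 (SE 0.102) and 0.05 (SE 0.130), with adjusted p = 0.393 and 0.810 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The METAP1D value turned to -0.049 without knockout library 2.

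The edit was an insertion of 179 bp at position 99035439 of chromosome 4. In the GRCh38 annotation (GENCODE release 29) this position lies in exon 4 of 11 (99035400 to 99035460) of METAP1, which spans 98995620 to 99062813 on the forward strand. The labels name METAP1D beside this coordinate, but METAP1D lies on chromosome 2 (171999583 to 172082430), and its RNA is described above. The labels give no build for the coordinate.

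**Figure D1:**
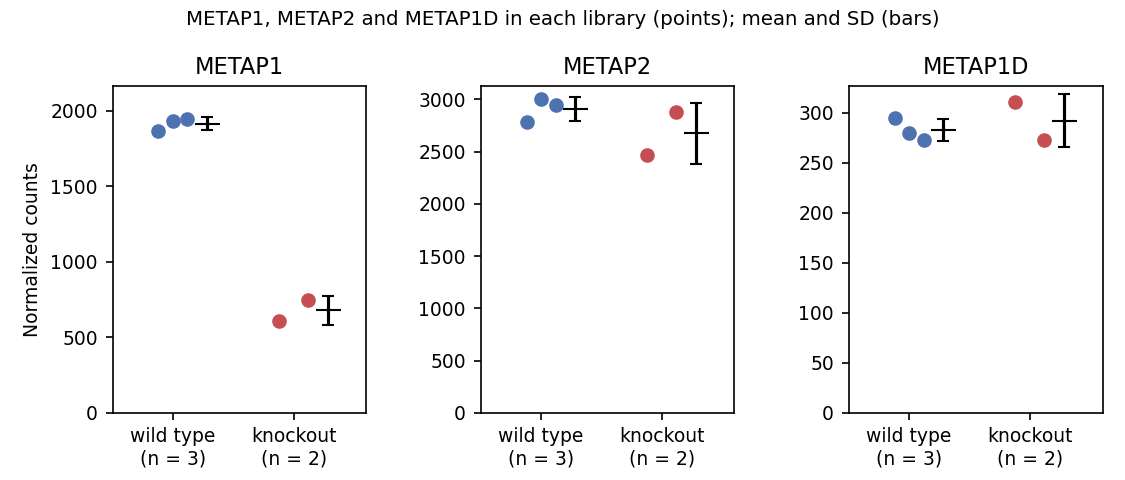
Normalized counts (vertical axes, from 0) of METAP1, METAP2 and METAP1D in the 3 wild type libraries (blue points) and the 2 knockout libraries (red points), with the group mean and SD as bars beside the points. METAP1 lay between 1868 and 1944 in wild type and at 611 and 748 in the knockout.

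Across the transcriptome, 3150 of 10620 tested genes (29.7%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1580 were higher and 1570 lower in the knockout, with 306 at least 2-fold higher and 224 at least 2-fold lower. LIN28A, which encodes an RNA-binding protein of stem cells and embryos, rose most among the genes named by the fixed rule, from 112 ± 17.6 normalized counts (SD, n = 3) to 4261 ± 112 (SD, n = 2). Among collagen genes, COL5A2 rose from 304 ± 52.4 to 7598 ± 627 and COL11A1 from 636 ± 126 to 4774 ± 399 (SD, n = 3 and 2). The metallothionein gene MT1E fell from 1659 ± 441 to 174 ± 85.8, and the histone gene HIST1H4A from 2951 ± 404 to 329 ± 37.3 (SD, n = 3 and 2).

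The 12 largest rises were LIN28A (log2 fold change 5.25, SE 0.136), COL5A2 (4.64, SE 0.148), PI15 (3.66, SE 0.305), CCND1 (3.47, SE 0.145), APOE (3.37, SE 0.196), COL11A1 (2.91, SE 0.161), TGFB2 (2.86, SE 0.170), IRS1 (2.85, SE 0.149), GSN (2.81, SE 0.134), FAM174B (2.81, SE 0.214), DSE (2.80, SE 0.142) and KRT8 (2.72, SE 0.152). Among them CCND1 encodes cyclin D1, APOE the lipid carrier apolipoprotein E, TGFB2 a transforming growth factor, IRS1 an adaptor of insulin signalling, GSN the actin-severing protein gelsolin and KRT8 a keratin of simple epithelia. The largest falls included MT1E (-3.25, SE 0.352), HIST1H4A (-3.16, SE 0.154), NR5A2 (-3.15, SE 0.167), HIST1H1D (-2.58, SE 0.108), KCNK2 (-2.43, SE 0.138), DCLK1 (-2.42, SE 0.148), BEX5 (-2.30, SE 0.190), RPL22L1 (-2.27, SE 0.110), CHD2 (-2.26, SE 0.201), HIST1H3A (-2.17, SE 0.111) and HIST4H4 (-2.17, SE 0.134). NR5A2 encodes an orphan nuclear receptor, KCNK2 a potassium channel, DCLK1 a microtubule-associated kinase, RPL22L1 a paralogue of ribosomal protein L22 and CHD2 a chromatin remodeller. The largest adjusted p among these genes was 0.000771, for MT1E, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all of these rises and falls kept their call whichever library was left out.

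**Figure D2:**
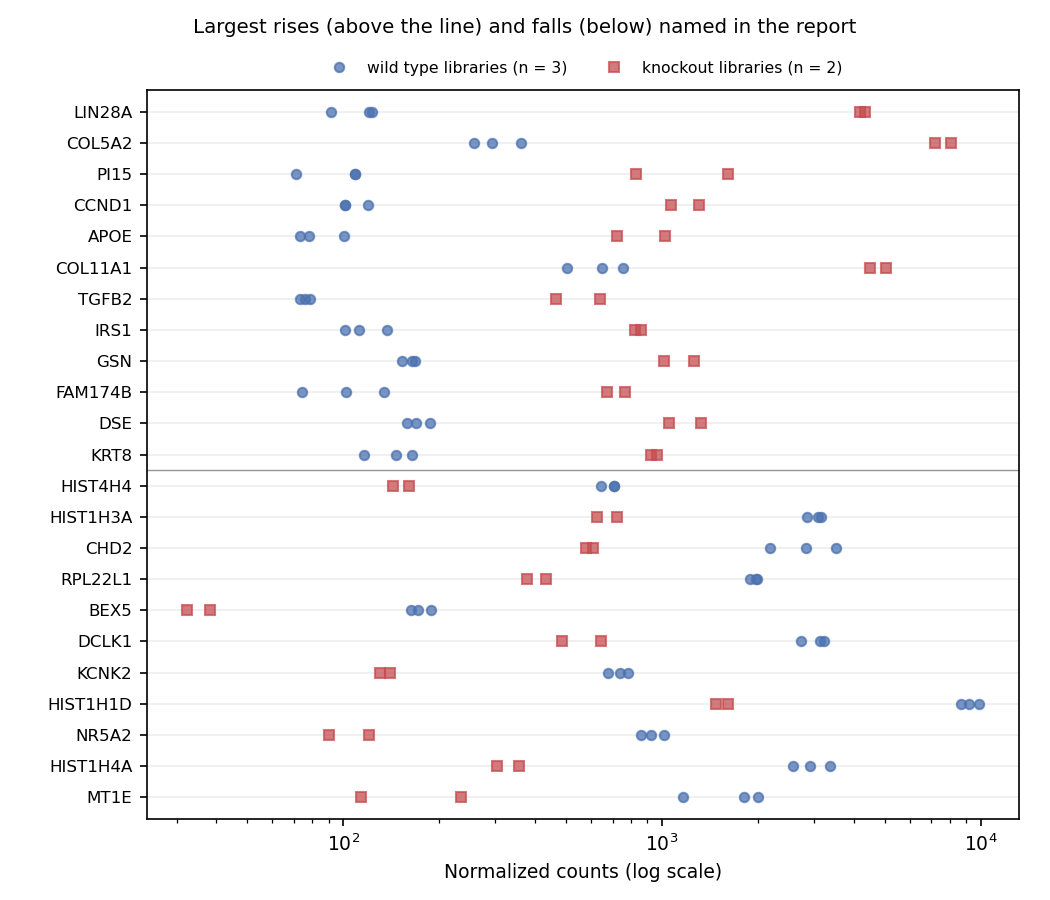
Normalized counts per library (horizontal axis, log scale) of the genes listed above with the largest rises and falls under the fixed rule, with 1 blue circle per wild type library and 1 red square per knockout library. The groups do not overlap in any of these genes, and LIN28A shows the widest gap (means of 112 and 4261).

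Of the 5 most abundant called genes, 4 fell: the glycolytic enzyme genes GAPDH (-1.09, SE 0.097) and ENO1 (-0.45, SE 0.115), the chaperone gene HSP90AB1 (-0.50, SE 0.093) and the linker histone gene HIST1H1C (-1.08, SE 0.089). The fifth, the deubiquitinase gene USP9X, rose by 1.05 (SE 0.108) on the log2 scale. The call of ENO1 was lost without wild type replicate 3 (-0.43) and without knockout library 2 (-0.47) or 3 (-0.43), and that of HSP90AB1 without knockout library 3 (-0.42).

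The number of calls rested on the few libraries. It was 1179 without knockout library 2, 1322 without knockout library 3 and 1665 without wild type replicate 3, against 4591 without wild type replicate 1. No gene called both with all libraries and with a library left out had the opposite sign. The groups did not overlap in 6301 tested genes (59.3%), where 20% is the share chance gives for 3 against 2 libraries. The authors' deposited table gave 3358 genes at the same threshold, 1679 in each direction, of which 3102 were among the 3150. The authors' deposited table gave METAP1 a log2 fold change of -1.44 and LIN28A 4.99.

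Replication-dependent histone genes fell as a group, with all 35 measured members lower in the knockout and a median log2 fold change of -1.51. These genes encode the histones made for new chromatin during S phase. HIST1H1D fell from 9229 ± 600 to 1539 ± 93.4 normalized counts, HIST1H4B from 4607 ± 126 to 1147 ± 34.1 and HIST1H3H from 1786 ± 45.9 to 401 ± 13.3 (SD, n = 3 and 2). The count was also 35 when adjusted over the list alone, and the list was called by camera (adjusted p = 9.06e-32) and remained so at adjusted p = 0.0379 with an estimated correlation. Histone genes are near-identical copies, so the split of reads between single members is uncertain.

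Genes of DNA replication and S phase fell too, 25 of 40 measured members, with none higher and a median of -0.42. FEN1, which encodes the flap endonuclease, fell from 2781 ± 114 to 1340 ± 28.0 normalized counts, and MCM2, a subunit of the replicative helicase, from 6349 ± 429 to 3659 ± 95.6 (SD, n = 3 and 2). CDC6 (-0.77, SE 0.095) and PCNA (-0.77, SE 0.096) were also lower. Adjusted over the list alone, 28 members fell, and with a library left out 12 to 27 were called lower. Camera gave adjusted p = 1.14e-10, and the list held at adjusted p = 0.0379 with an estimated correlation. Of the genes of G2 and mitosis, 13 of 38 fell (14 adjusted over the list alone, and 5 to 22 with a library left out) and none rose, with a median of -0.26. HMMR, a spindle-associated protein gene, had a log2 fold change of -1.66 (SE 0.139), KIF11 of -0.58 (SE 0.087) and CENPF of -0.60 (SE 0.090). That list was called by camera (adjusted p = 8.90e-05), with adjusted p = 0.604 with an estimated correlation.

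Genes of cholesterol synthesis and uptake were lower in the knockout: 21 of 23 measured members fell and 1 rose, with a median of -0.90. HMGCS1, which encodes the enzyme that makes HMG-CoA, fell from 6689 ± 252 to 2147 ± 12.3 normalized counts (SD, n = 3 and 2). ACAT2 (-1.30, SE 0.110) and HSD17B7 (-1.33, SE 0.134) were lower as well. SC5D, named here after its value was seen, was the member that rose (0.35, SE 0.103), and no member was called higher without wild type replicate 2 or 3 or either knockout library. SREBF2, the gene of the pathway's transcription factor, also named after its value was seen, had 0.40 (SE 0.151) and was not called. Adjusted over the list alone, 21 fell and 2 rose. Camera called the list (adjusted p = 1.66e-11), with adjusted p = 0.185 with an estimated correlation.

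Extracellular matrix and cell adhesion genes rose: 24 of 30 measured members were higher and 1 lower, with a median of 0.75. Beside COL5A2, the laminin gene LAMB1 rose from 1014 ± 50.4 to 3846 ± 41.6 normalized counts, the integrin gene ITGAV from 1701 ± 140 to 4589 ± 17.7 and the basement membrane gene NID2 from 468 ± 15.4 to 1135 ± 2.4 (SD, n = 3 and 2). LAMB2, named after its value was seen, was the member that fell (-0.40), and no member was called lower without wild type replicate 3 or knockout library 3. Adjusted over the list alone, 25 rose and 1 fell, and with a library left out 15 to 25 were called higher. The list was called by camera (adjusted p = 7.15e-12) and held at adjusted p = 0.0379 with an estimated correlation.

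Among markers of other cell types, 3 of 8 measured mesenchymal markers rose and none fell (3 adjusted over the list alone): S100A4 (2.44, SE 0.209), the cadherin gene CDH2 (0.78, SE 0.095) and the fibronectin gene FN1 (0.78, SE 0.098), both of the latter also counted among the matrix genes. Camera gave adjusted p = 0.0431 (median 0.46), with adjusted p = 0.556 with an estimated correlation. The call was lost without wild type replicate 1 (camera adjusted p = 0.0758) and with the length trend removed (median 0.32, camera adjusted p = 0.112). It was also lost without knockout library 2 (median 0.29). All 5 measured neural markers were called, in both directions (3 higher and 2 lower, and the same numbers adjusted over the list alone), among them NES, which encodes the intermediate filament protein nestin (1.01, SE 0.089), the 1 of the 4 named by the rule that kept its call whichever library was left out. Epithelial markers had 2 of 6 higher, KRT8 and KRT18 (2 higher and 1 lower adjusted over the list alone), and haematopoietic markers had 1 of 3 higher, KIT (1 adjusted over the list alone). Camera did not call these 3 lists, with adjusted p = 0.365, 0.134 and 0.943. KRT18 (0.41, SE 0.116) and KIT (0.56, SE 0.120) lost their calls without knockout library 2, at 0.51 for each, without knockout library 3 at 0.31 and 0.60, and without wild type replicate 3 at 0.43 and 0.55.

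The next 3 lists had small negative medians. Cytosolic ribosomal protein genes had 15 of 76 members lower and none higher (median -0.17; 10 lower adjusted over the list alone), with RPL29 at -0.54 (SE 0.090). Proteasome subunits had 11 of 35 lower and none higher (median -0.21; 13 lower adjusted over the list alone), with PSME1 at -0.65 (SE 0.110). Nuclear-encoded oxidative phosphorylation genes had 12 of 56 lower and 1 higher (median -0.29; 6 lower adjusted over the list alone), with NDUFB9 at -0.51 (SE 0.105). The counts of lower members depended on single libraries. Without wild type replicate 1 they were 49, 20 and 40 for ribosomal proteins, proteasome and oxidative phosphorylation, without knockout library 2 they were 1, 1 and 0, and without knockout library 3 they were 1, 3 and 0. NDUFB9 lost its call without knockout library 2 (-0.49) or 3 (-0.54). Camera called these 3 lists (adjusted p = 5.18e-05, 0.00100 and 2.76e-05), with adjusted p = 0.712, 0.663 and 0.712 with an estimated correlation. Camera adjusted p with a library left out was at most 0.00339, 0.00516 and 0.00141. The members are short genes (median lengths of 2040, 2750 and 1897 bases), and across all tested genes the fold change rose with gene length, from a median of -0.15 in the shortest 10% of genes to 0.21 in the longest 10%. This trend depended on the wild type library: the Spearman correlation of knockout minus wild type with gene length was 0.095 against wild type replicate 1, 0.359 against replicate 2 and 0.258 against replicate 3. With each library's length trend removed, the ribosomal protein list was no longer called (median -0.08, camera adjusted p = 0.0717), while the proteasome and oxidative phosphorylation lists were (medians -0.16 and -0.19). Reads of ribosomal protein and GAPDH pseudogenes could be counted with their parent genes, which adds uncertainty to single members.

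Endoplasmic reticulum unfolded protein response genes had 4 of 20 members lower and 2 higher (median -0.16; 8 lower and 2 higher adjusted over the list alone). The lower members included CRELD2 (-0.93, SE 0.119), MANF (-0.93, SE 0.120) and the calreticulin gene CALR (-0.66, SE 0.093). Interferon-stimulated genes had 6 of 17 lower and 1 higher (median -0.38; 8 lower and 1 higher adjusted over the list alone), with HLA-B at -0.88 (SE 0.092) and BST2 at -0.63 (SE 0.102). Heat shock protein genes had 2 of 18 lower, HSPE1 (-0.62, SE 0.107) and HSP90AB1, and 1 higher, BAG3 (0.39, SE 0.123), with a median of -0.24 and 2 lower adjusted over the list alone. Camera called the 3 lists (adjusted p = 0.0403, 0.0179 and 0.0291), with adjusted p = 0.556, 0.556 and 0.712 with an estimated correlation. With the length trend removed the medians were -0.18, -0.26 and -0.23 and camera adjusted p was 0.0717 for each. With a library left out, 3 to 11 unfolded protein response members and 2 to 10 interferon-stimulated genes were lower. The unfolded protein response list was not called without knockout library 2 (camera adjusted p = 0.0985). The heat shock list differed between the knockout libraries: its median was -0.46 with 8 members lower without knockout library 2, and -0.05 with 0 lower without knockout library 3 (camera adjusted p = 0.436), where HSPE1 stood at -0.53. BAG3 lost its call when wild type replicate 2 (0.34), wild type replicate 3 (0.38), knockout library 2 (0.35) or knockout library 3 (0.43) was left out.

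Enzymes that act on protein N termini showed few differences beside METAP1. Of 18 measured genes of methionine excision, deformylation, acetylation and myristoylation, NAA30 was higher (0.44, SE 0.105) and NAA20 lower (-0.52, SE 0.105), both being catalytic subunits of N-terminal acetyltransferases (1 higher and 2 lower, METAP1 included, also adjusted over the list alone). NAA30 was not called without wild type replicate 3 (0.45) or knockout library 2 (0.36), nor NAA20 without knockout library 2 (-0.49) or 3 (-0.55). The median of this list was 0.05 and its mean -0.05, and camera gave the direction of the mean, with adjusted p = 0.943. With a library left out, 0 to 4 were higher and 1 to 4 lower. Genes of N-degron recognition and the GID/CTLH ubiquitin ligase, which bind exposed protein ends, had 7 of 22 members higher and 1 lower (median 0.20; 8 higher and 1 lower adjusted over the list alone). YPEL5 (0.94, SE 0.116) and WDR26 (1.20, SE 0.173) were higher and MAEA was lower (1133 ± 33.2 to 689 ± 12.2 normalized counts), although all 3 belong to the same ligase. Camera called the list (adjusted p = 0.0403), with adjusted p = 0.604 with an estimated correlation, and did not without knockout library 2 (median 0.15, camera adjusted p = 0.0986), without wild type replicate 2 (median 0.16, camera adjusted p = 0.0629) or with the length trend removed (median 0.15, camera adjusted p = 0.112). The number of higher members ran from 2 to 9 with a library left out.

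The other lists were not called by camera. Targets of N-myristoylation had 7 of 29 higher and 3 lower, also when adjusted over the list alone, with the kinase gene FYN at 1.30 (SE 0.128). Methionine cycle and polyamine genes had 3 of 22 higher and 5 lower, also when adjusted over the list alone. The AHCY-like genes AHCYL2 (0.93, SE 0.137) and AHCYL1 (0.53, SE 0.087) were higher. CTH (-0.64, SE 0.132) and AMD1 (-0.41, SE 0.092) were lower. CTH lost its call without knockout library 2 (-0.66) or 3 (-0.61). AMD1 lost it without knockout library 2 (-0.41) or 3 (-0.42), or without wild type replicate 3 (-0.41). Targets of the integrated stress response had 5 of 31 higher and 5 lower (5 and 6 adjusted over the list alone), with VLDLR at 1.55 (SE 0.131), DDIT4 at 1.06 (SE 0.156), ATF4 itself at -0.90 (SE 0.116) and the serine synthesis gene PSPH at -0.80 (SE 0.110). Glycolysis and hypoxia genes had 3 of 30 higher and 6 lower, also when adjusted over the list alone, with LDHA at -0.74 (SE 0.093), ALDOA at -0.64 (SE 0.102) and the prolyl hydroxylase gene P4HA2 at 0.78 (SE 0.112). Their camera adjusted p-values were 0.243, 0.365, 0.648 and 0.245. With a library left out, 2 to 9 members were higher and 0 to 4 lower among targets of N-myristoylation, 2 to 3 and 0 to 7 for the methionine cycle, 3 to 5 and 2 to 8 for the stress response and 2 to 4 and 3 to 10 for glycolysis and hypoxia. Translation factors had 7 of 40 lower and none higher (4 lower adjusted over the list alone; camera adjusted p = 0.0916, and 0.0163 without wild type replicate 1). With a library left out, 0 to 10 were lower, and 0 when either knockout library was left out. EEF1B2 had -0.55 (SE 0.114), a call lost without knockout library 2 (-0.49) or 3 (-0.60). Aminopeptidases had 2 of 22 higher and 3 lower (5 and 4 adjusted over the list alone), and p53 targets 2 of 24 higher and 3 lower, also when adjusted over the list alone. Camera gave these lists adjusted p = 0.943 and 0.669, and none of the 8 members named by the rule kept its call whichever library was left out. Leaving out a library gave the aminopeptidases 0 to 5 higher and 0 to 5 lower members, and the p53 targets 0 to 4 and 0 to 3. The p53 targets differed between the knockout libraries, with a median of 0.28 without knockout library 2 and of -0.62 without knockout library 3, where camera called the list lower (adjusted p = 0.0188). Camera's direction differed in sign from the median also for the aminopeptidases (median -0.02, mean 0.01), p53 targets (median 0.01) and haematopoietic markers (median -0.19, mean 0.01).

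Of the 6 measured genes nearest to METAP1 in the list for its locus, TSPAN5 rose (0.89, SE 0.153) and EIF4E, the gene of the mRNA cap-binding factor, fell (-0.33, SE 0.104) beside METAP1 itself, also when adjusted over the list alone (camera adjusted p = 0.365). TSPAN5 lost its call without knockout library 2 (0.77), and EIF4E lost it when wild type replicate 2 (-0.30), wild type replicate 3 (-0.30), knockout library 2 (-0.27) or knockout library 3 (-0.39) was left out. Of 13 mitochondrially encoded mRNAs none was called, also when adjusted over the list alone, with MT-CO1 at 0.42 (SE 0.140) and MT-CO3 at -0.02 (SE 0.164). Their median was 0.42 and camera adjusted p 0.154. Without wild type replicate 1, 8 were higher and 1 lower (median 0.67, camera adjusted p = 0.00673), and without wild type replicate 2 none was called (median 0.15). A block by column numbers gave 10 higher and 1 lower (median 0.70, camera adjusted p = 0.000237). No knockout library carries number 1, so this block in effect sets wild type replicate 1 aside and is not separate evidence. With all libraries and no block, the estimated correlation between members was 0.917 and camera adjusted p with it 0.798. Whether these mRNAs differ is left open. Mitochondrial reads made up 0.549, 0.325 and 0.456% of the table's reads in wild type replicates 1 to 3 and 0.516 and 0.589% in the knockout libraries. No member of the list of abundant non-coding RNAs was measured.

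**Figure D3:**
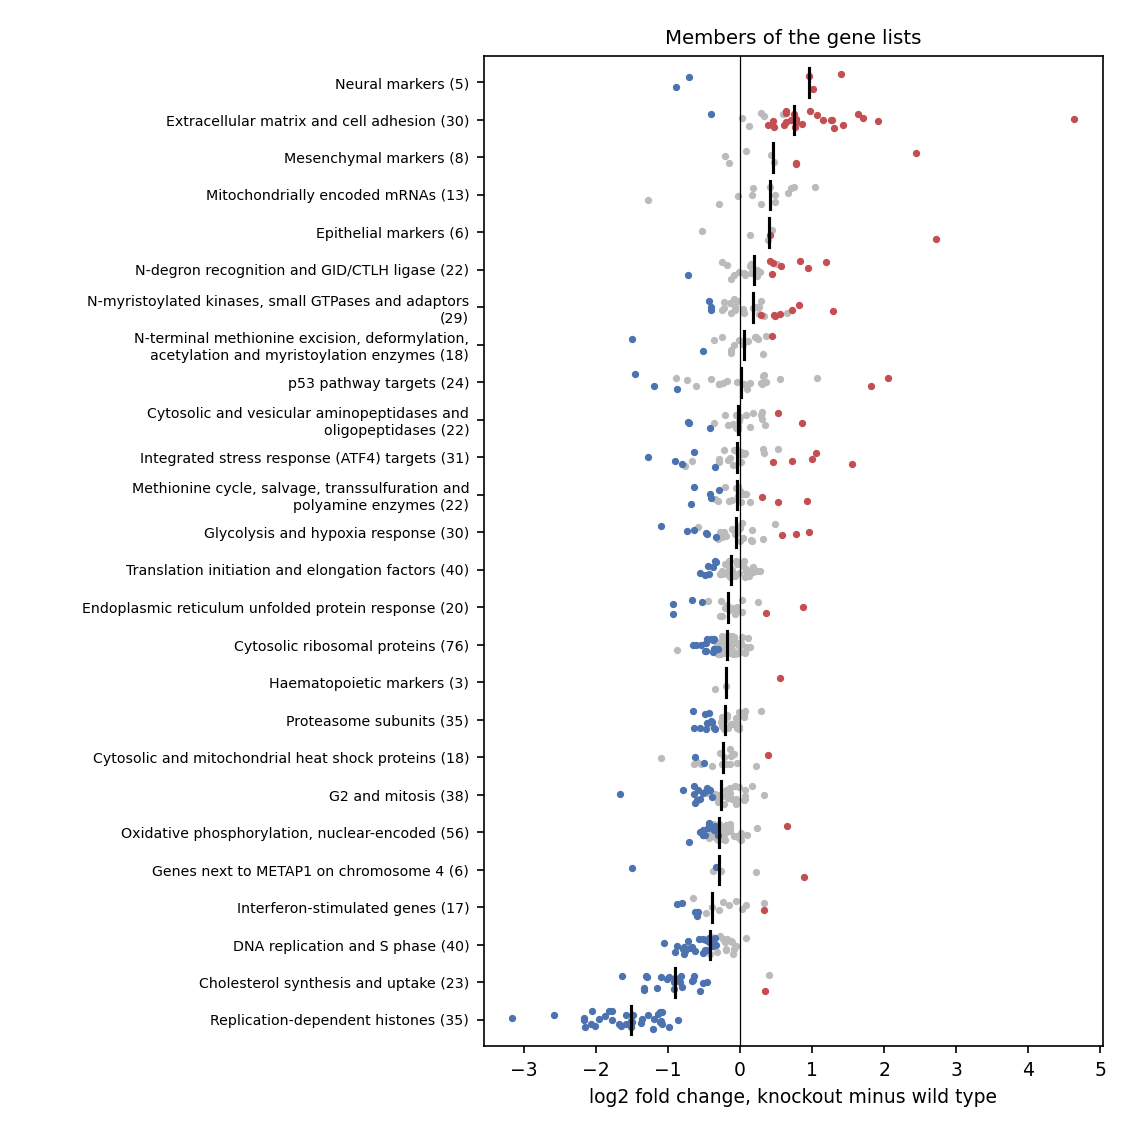
Log2 fold change (horizontal axis, knockout minus wild type) of each measured member of the 26 gene lists that had members in the table, with the number of members in parentheses and the median as a black bar. Red points were called higher, blue points called lower and grey points not called, and vertical scatter within a row has no meaning. All 35 replication-dependent histone genes lie left of 0 and 24 of 30 matrix and adhesion genes are red.

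The libraries separated by group first. The first principal component held 75.9% of the variance and placed the wild type libraries at -12.7, -27.4 and -21.7 and the knockout libraries at 31.4 and 30.5. The second held 13.8% and parted wild type replicate 1 (19.7) from wild type replicate 2 (-14.0). Across genes, which are not independent replicates, the difference between wild type replicates 1 and 2 had a Spearman correlation with gene length of 0.451, against 0.263 for knockout minus wild type and 0.104 between the knockout libraries. Histones, cholesterol, replication and matrix genes kept their camera calls without wild type replicate 1 and without wild type replicate 2, with medians of -1.57, -0.94, -0.45 and 0.76 without the former. With all libraries and an estimated correlation the cholesterol list was not called (camera adjusted p = 0.185).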

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

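Among the settings, the removal of length and GC trends, library sizes without TMM and the block by column numbers were chosen after the data were seen; the rest were planned. METAP1 stayed called and lower in all of them, between -1.65 and -1.36. The count of called genes lay between 3129 and 3457 under other scalings, filters, tools and trend corrections, and no gene shared with the 3150 had the opposite sign. The share of higher calls was 50.2%, and between 45.4 and 53.5% in these settings.

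Leaving out each library in turn gave 1179 to 4591 called genes. Of these, the genes higher in the knockout numbered 615 to 2313 and the genes lower in the knockout 564 to 2278. Fewer libraries lower the power, but why the count rose without wild type replicate 1 was not tested. Without a knockout library the remaining one is assumed to vary like the wild type. Called gene lists numbered 13, against 3 with an estimated correlation and 8 with the length trend removed. The former allows for the members' shared variation, but this cannot be all that lowered the number. Replication and matrix genes had estimated correlations of 0.00084 and -0.012, under the preset 0.01. Their camera adjusted p still rose from 1.14e-10 and 7.15e-12 to 0.0379. With the length trend removed, mitochondrially encoded mRNAs were called (camera adjusted p = 0.0471) while 6 lists were not. The median of the ribosomal protein list shrank from -0.17 to -0.08, of interferon-stimulated genes from -0.38 to -0.26 and of mesenchymal markers from 0.46 to 0.32. It changed less for the unfolded protein response (-0.16 to -0.18), heat shock (-0.24 to -0.23) and N-degron lists (0.20 to 0.15). Fry, another planned list test, did not call 6 of the 13: ribosomal proteins, oxidative phosphorylation, proteasome, G2 and mitosis, heat shock and N-degron. It called 2 lists that camera did not, epithelial markers (fry adjusted p = 0.00722) and targets of N-myristoylation (fry adjusted p = 0.0183). Cholesterol genes were called by fry (adjusted p = 0.00260).

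Results that changed sign were not called with all libraries. METAP1D ranged from -0.049 to 0.14 and MT-CO3 from -0.17 to 0.086 with a library left out, and MT-CO3 was 0.15 with the length trend removed. Camera adjusted p-values with a library left out ranged from 0.816 to 0.996 for aminopeptidases, 0.167 to 0.964 for stress response targets, 0.0188 to 0.841 for p53 targets (called lower without knockout library 3, with a median of -0.62, against 0.28 without knockout library 2) and 0.761 to 0.988 for haematopoietic markers. The direction also turned with the length trend removed for aminopeptidases (0.898) and p53 targets (0.994) and with the GC trend removed for aminopeptidases (0.986). The cause was not tested.

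The planned block by the numbers in the titles was not run, since the knockout columns do not carry them. A replicate block by column numbers called 4356 genes, with MT-CO3 at 0.11 and p53 targets at 0.685. No knockout column is numbered 1, so wild type replicate 1 stood alone in its block and did not inform the fold changes. That setting is thus close to leaving this library out, which called 4591 genes. Deviations of same-numbered libraries correlated at 0.03 for number 2 and -0.0025 for number 3. The deviations of the 2 knockout libraries mirror each other, so these values cannot decide whether same-numbered libraries shared a day or culture.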

Other observations

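The gene groups and chromosome regions below were chosen after the fold changes were seen. The tests of copy number inside narrower blocks were also chosen after their values were seen, and the other tests had their predictions written before. All 4 measured metallothionein genes, which encode small metal-binding proteins, were lower in the knockout, with a median log2 fold change of -2.07. Beside MT1E, MT2A fell from 780 ± 128 to 176 ± 59.7 normalized counts, and MT1M from 132 ± 32.5 to 33.0 ± 4.19 (SD, n = 3 and 2), and MT1X had a log2 fold change of -1.23 (SE 0.207). All 4 kept their call whichever library was left out. They are close paralogs, and reads shared between them were not examined. Of 13 immediate early genes, FOS (-1.34, SE 0.362) and FOSB (-1.99, SE 0.352) fell and NR4A1 rose (0.55, SE 0.134). FOS kept its call only without wild type replicate 3. FOSB lost it without wild type replicate 2 or knockout library 3, and NR4A1 without wild type replicate 3 or either knockout library. This group had 3 higher and 1 lower without wild type replicate 1 and no call without knockout library 3, and its median of 0.07 turned to -0.17 without wild type replicate 3, which leaves its direction undecided.

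In a scan of neighbouring genes, 3 regions had a window median larger in size than 0.402, the 95th percentile of the largest window median per gene-order permutation. On chromosome 6 (20401906 to 28302549, GRCh38) the 38 genes included 13 histone genes, and the strongest window had a median of -0.64. Genes without a position were not scanned, among them HIST1H4A, HIST1H3A, HIST1H4B and HIST1H3H, so histone genes of this region may be undercounted. On chromosome 19 (55476332 to 58550722) the 50 genes included 41 genes of zinc finger DNA-binding proteins, of which 20 rose and 1 fell. On the X chromosome (77826364 to 108091618) 24 of 52 genes fell and 5 rose, among them all 7 measured BEX and TCEAL genes, which fell. Without each library in turn the zinc finger genes had 7 to 22 higher, the lowest number without knockout library 3, and the BEX and TCEAL genes 4 to 7 lower, the lowest without knockout library 2. Whole-chromosome medians lay between -0.08 and 0.08.

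A length-dependent difference in library yield was weighed for 7 of the 13 called lists, named below, since the fold change rose with gene length and wild type libraries differed by length among themselves. After each library's length trend was removed, the median kept 0.896 of its size for histones (95% interval 0.819 to 0.942), 0.958 for replication genes (0.812 to 1.154), 0.904 for cholesterol genes (0.87 to 1.081) and 0.84 for matrix genes (0.706 to 0.998). This argues against length as the whole cause of those 4 patterns. Ribosomal protein, oxidative phosphorylation and proteasome genes together kept 0.698 (0.571 to 0.813), from -0.22 to -0.15, so length may account for part of their fall. The ribosomal protein list was not called after the removal, with a median of -0.08 against -0.17. A difference of the edited clone that is unrelated to METAP1 stays open for all of these, as do effects of METAP1 loss.

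For the zinc finger genes of chromosome 19, a copy number difference of the whole region was weighed with the other genes. The 9 others had a median of 0.07 against 0.46, a difference of -0.385 (95% interval -0.936 to -0.091). The zinc finger genes were chosen after their rise was seen, which favours such a difference. Only 2 of the 9 others lie in the strongest window, against 18 of the 20 zinc finger genes that rose. The contrast thus mixes kind of gene with position, so this interval does not decide. A gain limited to the strongest window (55675226 to 57916610) cannot be told apart, since only 2 genes in it are not zinc finger genes, and they differ: EPN1 was higher (0.69, SE 0.194) and TRAPPC2P1 was not called (-0.0075). A rise of zinc finger genes wherever they lie also cannot be told apart: the 330 elsewhere had a median of 0.12, which is 0.268 of that in the region (0.161 to 0.72). Reads shared between these paralogs were not tested.

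For the X chromosome genes, a copy number loss of the region as the whole cause was weighed with its other 45 genes. Their median of -0.19 lay 0.693 above that of the BEX and TCEAL genes (95% interval 0.149 to 1.584). Of these others 17 fell and 5 rose, so they lean the same way. The family was chosen after its fall was seen, which favours such a gap, so this interval does not decide. A smaller loss of the block between the outermost BEX and TCEAL genes (102153708 to 103630953) is argued against by the 5 other genes inside it, whose own median was 0.76. That median lay 1.649 above the family (0.554 to 2.432), and GPRASP2 (1.13, SE 0.121) and BHLHB9 (0.84, SE 0.160) rose. All 5 lie between BEX5 and BEX4. A loss of only the stretch from BEX4 to TCEAL1 (103215092 to 103630953) cannot be told apart, since the block has no other measured gene there. Such a loss would leave BEX5, which also fell, outside it. Shared regulation of this gene family, in the clone or after METAP1 loss, may remain as a hypothesis and was not tested.

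LIN28A blocks the maturation of let-7 microRNAs, so a hypothesis is that let-7 target mRNAs were released in the knockout. Its paralogue LIN28B, itself among the targets tested below, had 2024 ± 249 and 2395 ± 273 normalized counts (SD, n = 3 and 2). LIN28B was not called (0.24, SE 0.128). Wild type cells thus already held more LIN28B reads than LIN28A reads (112 ± 17.6, SD, n = 3), which limits this hypothesis. Of 39 listed targets, a list that leaves out CCND1 and FIGN because their rise had been seen, 33 were measured, and 9 rose and 1 fell, with a median of 0.12 (95% interval 0.039 to 0.273). With a library left out, 3 to 12 rose and 0 to 4 fell, with medians of 0.069 to 0.17, the fewest rises without knockout library 2. Camera gave p = 0.0421 with the preset correlation and p = 0.178 with an estimated correlation, and p = 0.0673 with the preset correlation without knockout library 3. TRIM71 (1.21, SE 0.142), ARID3B (1.15, SE 0.175) and IGF2BP2 (0.82, SE 0.128) kept their call whichever library was left out, while RRM2 (-0.33, SE 0.089) fell but lost its call without wild type replicate 3 or either knockout library. The values are consistent with a small release, but the test rests on the preset correlation, let-7 itself was not measured, and genes active in the same cell state could move with LIN28A.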
